A study of Mus musculus with 18 samples.

How the data were processed

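RNA was sequenced on an Illumina HiSeq 2000 from thymic epithelial cells of mice aged 6 to 8 weeks. Per the labels, stroma was enriched from digested thymi and flow cytometry separated cortical thymic epithelial cells (cTEC) from medullary thymic epithelial cells of the lo and hi gates (mTEClo, mTEChi). The labels do not say which surface protein the lo and hi gates measure. Each population was taken from wild-type (WT) mice and from mice with a targeted deletion in Aire (KO), with 3 libraries per group and 18 libraries in all. The strain label is that of the Aire mutant line for every sample, WT samples included. The labels do not say whether the replicates of a group came from separate mice or preparations, so the p-values here measure only the spread between these libraries.

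For every library the authors deposited 1 table of 23063 genes with chromosome, start, end, symbol, RPKM and a number of aligned bases. The authors' RPKM values are bases on the gene per kilobase of gene model, divided by a library-wide total. Each library was tested against WT cTEC replicate 1, on 6962 to 8812 genes with higher RPKM in both. The ratio of the bases to the RPKM differed by 1 constant for all these genes, and genes with lower RPKM were not checked. The last column of the deposited tables holds a signal, the aligned bases summed over the gene, and not read counts. Between 9.72% and 18.81% of the values up to 2000 bases were whole multiples of 100 bases, so whole reads could not be recovered and tests for read counts were not run. The genome build mm10 and CASAVA 1.8.2 are named in the submitters' processing notes. The annotation and the aligner settings are not given in the sources used here. Each symbol has 1 value, except 12 symbols that stand in more than 1 place, and values of single exons, alleles or transcripts are not given.

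Depth was taken as the aligned bases on genes. It ran from 4.54 to 18.1 Gb per library. Both extremes were WT mTEClo libraries. At such depth the spread between libraries, and not counting error, limits the precision for most genes, and no counting interval is given since the values are not counts. Reads shared between paralogs cannot be separated from these tables, which limits single values in families such as the major urinary proteins, and for genes with many pseudogenes.

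The deposited RPKM were used without rescaling. Genes with at least 0.1 RPKM in at least 3 of the 18 libraries were tested (19451 genes), and log2(RPKM + 0.1) was modelled with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with a trend). The model had 6 group means and used all 18 libraries, so that each comparison shared 1 estimate of the spread per gene. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The 10 comparisons were KO minus WT in each population, the differences between populations within a genotype, and the difference between the genotype effect in mTEChi and that in mTEClo or cTEC. Log2 fold changes of genes at or near 0 RPKM in a group depend on the added 0.1 and are no lower bounds. The same holds for the median of a list that has such members.

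For 37 gene lists (543 entries, 7 of them not in the tables), limma's camera compared each list's genes with all other tested genes, with a preset correlation between genes of 0.01 and again with an estimated correlation. The lists covered thymic epithelial markers, antigen presentation, tuft and keratinocyte genes, chemokines, 15 sets of tissue-restricted genes, antigens commonly assayed in studies of Aire, genes linked to Fezf2, partners of Aire, the NF-kB and TNF superfamily, proliferation, interferon-stimulated and housekeeping genes, dissociation stress, and markers of 6 other cell types. Lists needed at least 4 tested members, and the erythroid list was not tested. Adjusted p-values of lists are over the lists of a comparison. fry, the second list test, asks whether the genes of a list move on balance one way and does not compare them with other genes. For each list the members called over all tested genes are counted, and beside them those called when adjusted over the list alone. The lists, the tests, the comparisons and the rule for naming genes were fixed before the data were examined.

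Named genes are Aire, the 10 genes with the largest rise and the 10 with the largest fall for KO minus WT in mTEChi, and the 5 and 5 of each other comparison. These had to be called, with no overlap between the libraries of the groups, a mean of at least 1 RPKM in the higher group, and a symbol that is not a predicted gene model, a small RNA or an antigen receptor segment. From lists that passed, up to 3 members with the smallest adjusted p are named. From other lists, the member with the smallest adjusted p and the highest member that was not called are named. Values of 2 genes are not reported here. The commonly assayed antigens are all named for KO minus WT in mTEChi.

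Detected genes were counted as those with at least 0.1 RPKM in a library and compared by an exact 2-sided permutation test, whose smallest p for 3 against 3 libraries is 0.1. Aire-independent mTEChi genes were those higher in KO mTEChi than in KO cTEC by a log2 fold change of at least 1 whose genotype difference in mTEChi was not called and had a 95% interval within plus or minus 1. Chromosomal clustering was compared with 1000 random sets of tested genes matched on 10 expression classes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for reading the tables, for the permutation tests and for the plots.

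The model was tested on simulated data in which 200 genes per comparison were changed by 2-fold or 4-fold and each gene had 1 residual SD in all groups. It recovered 55% to 89% of the 2-fold and 89% to 100% of the 4-fold changes. It also called 48 unchanged genes for KO minus WT in mTEChi and 55 for mTEChi minus mTEClo in WT, up to 23.0% of the calls. Models with only the libraries of the compared groups made 3 to 11 such calls. The simulation does not cover a group with a larger spread than the others, as the KO cTEC libraries had.

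The alternatives were pseudocounts of 0.01 and 1, no filter and a filter at 1 RPKM, upper-quartile scaling, quantile normalization, an added 2-fold threshold, robust eBayes, only the compared groups in the model, and the replicate number as a block, alone or within genotype. Each replicate was also left out in turn. After the values were seen, centring on the housekeeping list, voom on read equivalents (aligned bases divided by 100), and fits without KO cTEC replicate 1 were added.

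Replicate numbers are not stated to mark shared animals. Of the 15 pairs of groups, only WT cTEC with WT mTEClo had a correlation above 0.1 for every same-numbered pair of libraries once group means were removed (r = 0.107, 0.168 and 0.154, across genes), so the replicate block was kept as an alternative. Between populations of a genotype, however, the library with the same number was the best match in 16 of 18 comparisons, with every same-numbered r above 0, against 1 of 27 comparisons across genotypes. This is a hint from the data that populations of a genotype share preparations by number. Pearson correlations between replicates of a group ran from 0.971 to 0.995 across genes, and no library was a copy of another.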

Results

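Expression of 23063 genes was measured in 6 groups of 3 libraries each: cTEC, mTEClo and mTEChi from WT and from Aire KO mice. The series title contrasts promiscuous expression, the transcription of tissue-restricted genes in thymic epithelium, that Aire induces with that which is independent of Aire. Depth was 11.1 ± 0.336 Gb in WT cTEC, 10.1 ± 1.14 Gb in KO cTEC, 10.2 ± 7.1 Gb in WT mTEClo, 7.9 ± 1.48 Gb in KO mTEClo, 13.3 ± 2.41 Gb in WT mTEChi and 9.31 ± 2.77 Gb in KO mTEChi. Values with ± are mean and SD over the 3 libraries of a group. Levels are RPKM, and fold changes are on the log2 scale of RPKM + 0.1 unless a level is given.

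The breadth of expression was compared first. WT mTEChi detected 19501 ± 66 genes at 0.1 RPKM or more, KO mTEChi 16467 ± 42, WT mTEClo 16374 ± 66.3, KO mTEClo 16358 ± 116, WT cTEC 15689 ± 236 and KO cTEC 16061 ± 219. KO mTEChi thus detected 3034 fewer genes than WT mTEChi, a difference larger than the spread between replicates (exact permutation p = 0.1, the smallest that 3 against 3 libraries can give). WT mTEChi also exceeded WT mTEClo by 3127 genes and WT cTEC by 3812 (exact permutation p = 0.1 for both), and WT mTEClo exceeded WT cTEC by 686 (exact permutation p = 0.1). In the KO, mTEChi exceeded mTEClo by 109 genes (exact permutation p = 0.3) and cTEC by 406 (exact permutation p = 0.1), but at 1 RPKM or more these differences were -250 and -202. The genotypes differed by -16.3 genes in mTEClo (exact permutation p = 0.8), which was 106 at 1 RPKM or more. In cTEC the KO libraries detected 373 more genes (exact permutation p = 0.1), but 490 fewer when every gene above 0 was counted, a difference of -490.

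**Figure D1:**
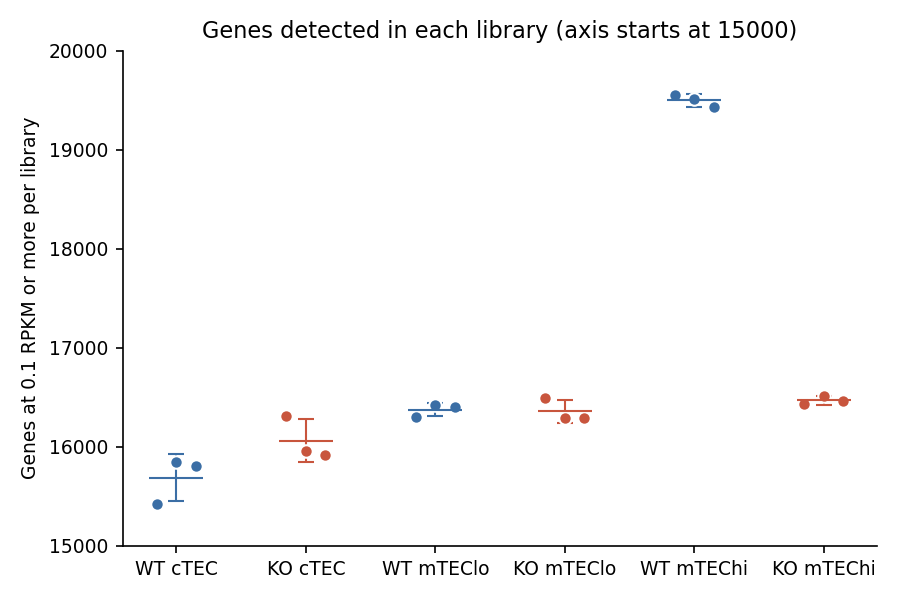
Number of genes with at least 0.1 RPKM in each library (points), with group mean and SD (bars, n = 3), for WT (blue) and KO (red) cTEC, mTEClo and mTEChi. The WT mTEChi libraries detect 19428 to 19558 genes, and every other library at most 16512.

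The first comparison asks which genes differ between KO and WT mTEChi. The hormone genes Ins2, Sst and Ppy fell from over 15 RPKM in WT to under 0.1 RPKM in KO mTEChi. Ins2, which encodes insulin (chromosome 7), was at 15.6 ± 4.16 RPKM in WT and 0.0217 ± 0.0264 in KO mTEChi. Sst, which encodes somatostatin, was at 31 ± 1.73 and 0.00393 ± 0.00681, and Ppy, which encodes pancreatic polypeptide, at 25.8 ± 6.85 in WT and listed at 0 in every KO library. Of 19451 genes tested, 10269 were called lower and 1862 higher in KO mTEChi, of which 5741 and 411 changed by 2-fold or more. The median over all tested genes was -0.39, and quantile normalization, which makes the distributions alike, moved it to 0.08 and the counts to 4808 lower and 6064 higher, 55.8% of the calls against 15.3%. Among genes at 0.587 to 3.83 RPKM in WT mTEChi, the 2597 not higher in mTEChi than in cTEC had a median of -0.53 and the 3276 higher there one of -1.62, the same WT libraries entering the choice and the change. Directions of single genes and of lists below hold under every scaling tried unless stated, and the size of a change is relative to that shift.

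**Figure D2:**
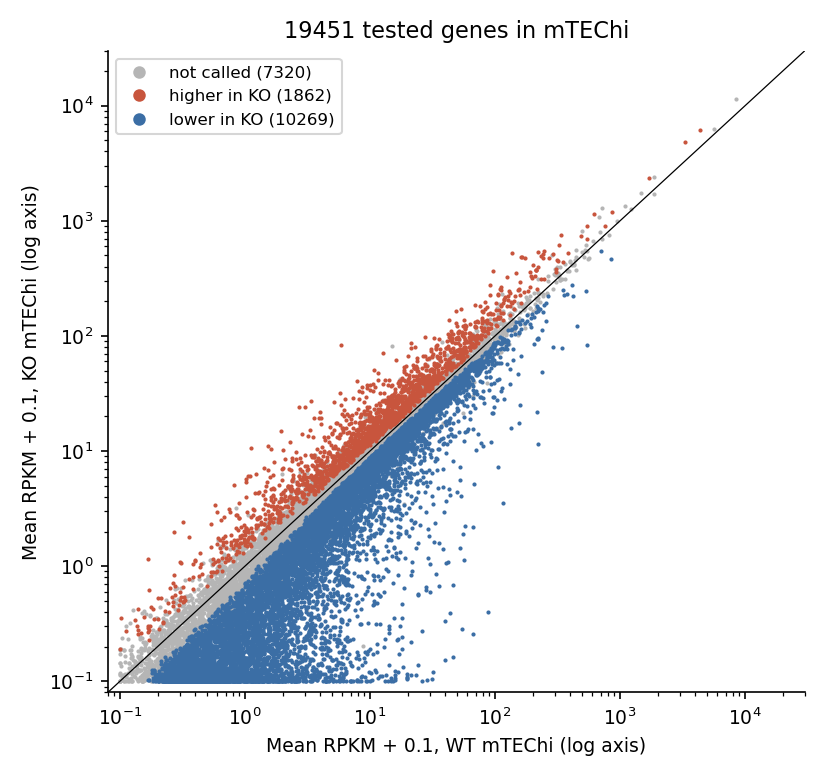
Mean RPKM + 0.1 of the 19451 tested genes in WT (x) and KO (y) mTEChi, both on log axes, n = 3 libraries per group, with the diagonal of equal values. The 10269 genes called lower in KO (blue) reach the floor of the plot, and 1862 were called higher (red).

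Besides Sst and Ppy, the 10 largest falls were those of Crabp1, Nts, Cytl1, Tac2, Sbpl, Spt1, Gstm3 and Pgc. Nts, which encodes the peptide neurotensin, went from 66.7 ± 4.25 to 0.157 ± 0.105 RPKM (log2 fold change -8.10, SE 0.394, adjusted p = 8.2e-11). Crabp1, a retinoic acid binding protein, went from 46 ± 6.83 to 0.0613 ± 0.0435 (-8.19, adjusted p = 1.9e-10). Pgc, the gene of a gastric pepsinogen, went from 54.8 ± 5.35 to 0.183 ± 0.0513 RPKM (-7.61, adjusted p = 7.5e-13). Tac2, which encodes a tachykinin, was at 39.9 ± 7.85 RPKM in WT and at 0.0524 ± 0.0423 in KO. Cytl1 fell from 28.4 ± 6.77, Sbpl from 31.6 ± 7.2 and Gstm3, a glutathione transferase gene, from 23 ± 2.8 RPKM, each to under 0.1 RPKM. The largest rise was that of Ctla4 (chromosome 1), which encodes an inhibitory receptor of T cells, from 5.78 ± 0.577 to 83.3 ± 1.65 RPKM (3.83, SE 0.393, adjusted p = 4.5e-07). Fam19a1 rose from 2.91 ± 0.342 to 23.8 ± 1.02 RPKM, Acot12, an acetyl-CoA hydrolase gene, from 1.42 ± 0.0735 to 10.9 ± 0.344, and Rgr, an opsin of the eye, from 1.51 ± 0.0344 to 10.3 ± 0.646. The olfactory receptor genes Olfr1138 (2.93) and Olfr1140 (2.54), and Nfam1 (2.63), Ppp1r3c (2.53), Defb33 (2.51) and Ptchd4 complete the 10 largest rises. Defb33 lost its call with a pseudocount of 0.01 (2.79).

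Aire itself (chromosome 10, 78030022 to 78043610) was at 677 ± 17.9 RPKM in WT and 1073 ± 64.5 in KO mTEChi (log2 fold change 0.66, SE 0.428, adjusted p = 0.19). The tables give 1 value for the gene, so the deleted part cannot be separated from the rest, and the value does not check the genotype labels.

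**Figure D3:**
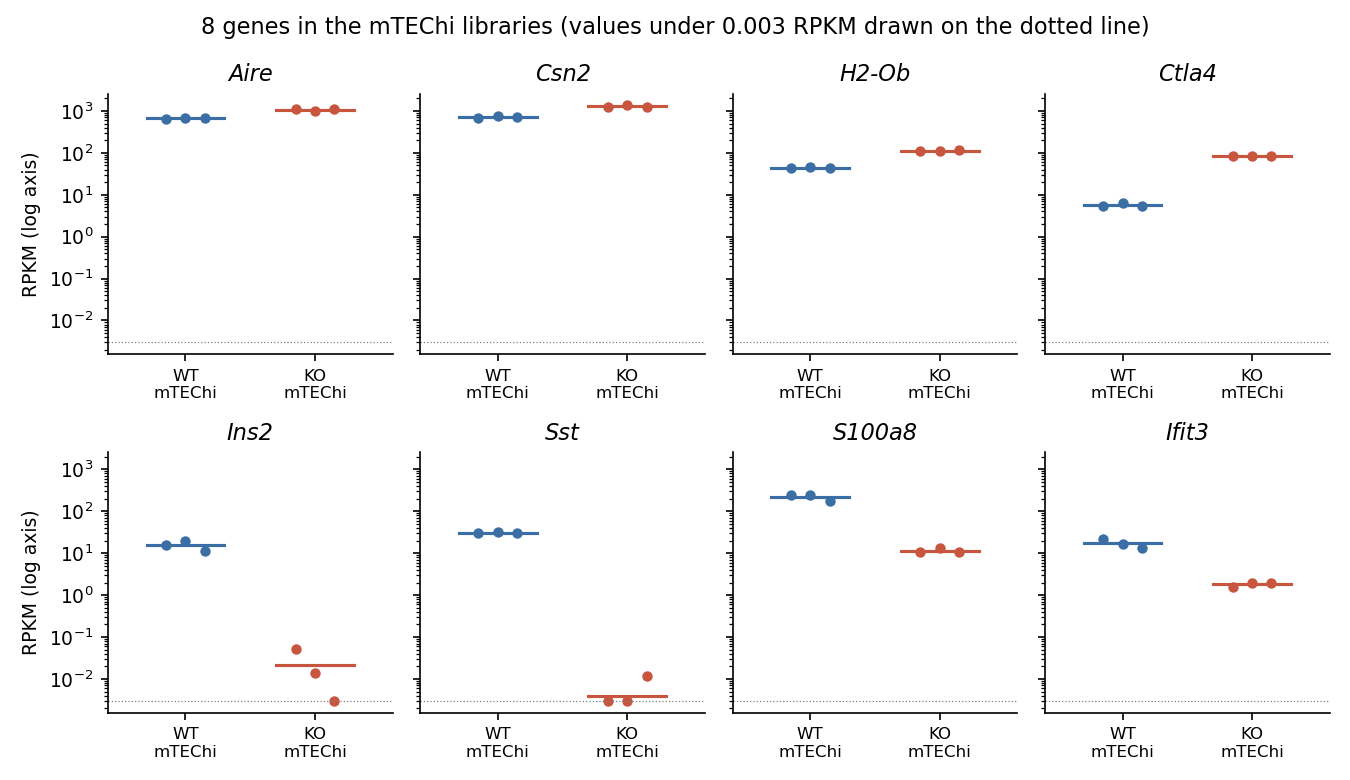
RPKM of 8 genes in the WT (blue) and KO (red) mTEChi libraries on a log axis (points, 3 libraries per group, lines at the group means, values near 0 drawn on the dotted line). Ins2 and Sst stand above 10 RPKM in each WT library and below 0.1 in each KO library, while Ctla4 rises from 5.78 to 83.3.

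Lists of tissue-restricted genes fell in KO mTEChi, and 10 of them did so more than other genes. Of 19 pancreatic acinar genes, 17 fell (17 adjusted over the list alone), among them Reg2 from 11.9 ± 3.34 to 0.0112 ± 0.0193 RPKM (camera adjusted p = 0.00059, and adjusted p = 0.086 with an estimated correlation). All but 3 of 24 stomach and intestine genes fell (21, and 21 adjusted over the list alone, camera adjusted p = 0.00067, and adjusted p = 0.086 with an estimated correlation). Gkn2, a gastrokine, went from 7.81 ± 1 RPKM to a value listed at 0 in every KO library. Salivary and lacrimal genes fell in 14 of 16 cases (15 adjusted over the list alone, camera adjusted p = 0.00027, and adjusted p = 0.058 with an estimated correlation). Smr3a was at 2.91 ± 0.543 in WT and listed at 0 in KO. Liver genes fell in 19 of 23 cases (19 adjusted over the list alone, camera adjusted p = 0.0014, and adjusted p = 0.086 with an estimated correlation). The albumin gene Alb went from 8.06 ± 2.3 to 0.0575 ± 0.0657 RPKM, and the fibrinogen gene Fga from 2.93 ± 0.047 to 0.00202 ± 0.0021. In the islet list 10 of 13 fell (11 adjusted over the list alone, camera adjusted p = 0.018, and adjusted p = 0.086 with an estimated correlation).

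Eye genes fell in 16 of 18 cases (17 adjusted over the list alone, camera adjusted p = 0.0012, and adjusted p = 0.086 with an estimated correlation). Cryba1, a lens crystallin gene, went from 3.44 ± 0.26 to 0.0111 ± 0.0192 RPKM. Seminal vesicle and prostate genes fell in 11 of 12 cases (11 adjusted over the list alone, camera adjusted p = 0.0012, and adjusted p = 0.086 with an estimated correlation). Svs4 was at 5.54 ± 0.715 and 0.0104 ± 0.0101. Of 7 tested major urinary protein genes 6 fell (7 adjusted over the list alone, camera adjusted p = 0.0017, and adjusted p = 0.066 with an estimated correlation). Mup4 was at 2.29 ± 0.565 in WT and listed at 0 in KO. Lung and airway genes fell in 13 of 14 cases (13 adjusted over the list alone, camera adjusted p = 0.0022, and adjusted p = 0.21 with an estimated correlation). The surfactant gene Sftpb went from 2.83 ± 0.931 to 0.0111 ± 0.00996 RPKM. Kidney genes fell in 10 of 11 cases (10 adjusted over the list alone, camera adjusted p = 0.0029, and adjusted p = 0.12 with an estimated correlation). Kap was at 3.31 ± 0.45 in WT and listed at 0 in KO.

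Other tissue lists did not pass camera. The called lower members were 6 of 8 milk protein genes (6 adjusted over the list alone, camera adjusted p = 0.11), 11 of 16 thyroid, adrenal and pituitary genes (12; 0.14), 11 of 19 brain genes (11; 0.17), 12 of 21 muscle genes (12; 0.86) and 9 of 19 testis and germ cell genes (9; 0.86), in parentheses the count adjusted over the list alone and the camera adjusted p. The testis list had a median of -1.26 that was 0.21 after quantile normalization. Csn2, the gene of the milk protein beta-casein, was not called, at 720 ± 37.5 RPKM in WT and 1287 ± 63.6 in KO (0.84, adjusted p = 0.076). Actn3, a muscle actinin gene, was at 131 ± 6.28 and 159 ± 8.86 (0.28, adjusted p = 0.22).

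Among the 12 antigens commonly assayed in studies of Aire, 11 were tested and 6 fell (6 adjusted over the list alone, camera adjusted p = 0.44). Spt1, a salivary protein gene, fell from 87 ± 10.4 to 0.298 ± 0.145 RPKM (-7.82, adjusted p = 6.1e-09) and S100a8, a calgranulin gene, from 222 ± 35.3 to 11.5 ± 1.49 (-4.25, adjusted p = 3.4e-07). Tff3, a trefoil factor gene, fell from 52.3 ± 11.3 to 1.33 ± 1.25 (-5.58, adjusted p = 2.3e-05). Ins2 is given above. Obp1a was at 1.16 ± 0.232 RPKM in WT and listed at 0 in KO (adjusted p = 0.00049). Crp, the C-reactive protein gene, fell from 9.48 ± 1.38 to 5.19 ± 1.19 (-0.87, adjusted p = 0.024), a call lost after quantile normalization (-0.57), when centred on the housekeeping list (-0.75) and without WT replicate 1 (-0.82), WT replicate 3 (-0.80) or KO replicate 3 (-0.68). Csn2, Fabp9 (55.8 ± 6.66 and 21.3 ± 0.583, adjusted p = 0.088), Resp18 (122 ± 7.54 and 101 ± 8.35, adjusted p = 0.64), Gad1 (12 ± 0.511 and 8.38 ± 0.318, adjusted p = 0.23) and Ttr (4.42 ± 1.08 and 3.14 ± 1.18, adjusted p = 0.32) were not called. The log2 fold change of Ttr, -0.52, was 0.07 after quantile normalization.

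Genes of antigen presentation by MHC class II rose in KO mTEChi in 9 of 10 cases (9 adjusted over the list alone, camera adjusted p = 1.0e-06, and adjusted p = 0.086 with an estimated correlation). H2-Ob rose from 44.2 ± 0.55 to 111 ± 2.73 RPKM, H2-Oa from 214 ± 10.8 to 375 ± 19.4, both subunits of the peptide-loading regulator DO, and H2-DMb1 from 119 ± 7.78 to 208 ± 6.07. The mature mTEC list, which includes Aire, rose in 5 of 14 cases (1 adjusted over the list alone, camera adjusted p = 0.00027, and adjusted p = 0.35 with an estimated correlation). Its members Ciita, the class II transactivator gene, rose from 69 ± 4.8 to 93.6 ± 4.06 RPKM (0.44, adjusted p = 0.0019), Ctss, a cathepsin gene, from 132 ± 5.29 to 237 ± 18.3 (0.84, adjusted p = 0.021) and Pdcd1lg2, a ligand of PD-1, from 13 ± 0.654 to 19.6 ± 0.594 (0.59, adjusted p = 0.026). Ctss lost its call after quantile normalization (0.73) and without WT replicate 2 (0.82), WT replicate 3 (0.83) or KO replicate 2 (0.78). Pdcd1lg2 lost it without WT replicate 2 (0.60), WT replicate 3 (0.55) or any 1 KO replicate (0.57 to 0.61). The NF-kB and TNF superfamily list had 4 of 13 higher and 3 lower members (4 and 3 adjusted over the list alone, camera adjusted p = 0.0012, and adjusted p = 0.44 with an estimated correlation). Traf6, a signal adaptor gene, rose from 25.2 ± 1.83 to 40 ± 1.65 RPKM and Nfkbia, an inhibitor of NF-kB, from 620 ± 29.1 to 1151 ± 19. Ltbr, the lymphotoxin beta receptor gene, fell from 18.5 ± 0.726 to 11.2 ± 0.092. The dissociation stress list passed upward with no member called (camera adjusted p = 0.044, and adjusted p = 0.67 with an estimated correlation). Its median was 0.06, which quantile normalization turns to -0.09, and camera sets the list against the downward balance of all other genes.

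Interferon-stimulated genes fell in 11 of 14 cases and 1 rose (11 and 1 adjusted over the list alone, camera adjusted p = 0.047, adjusted p = 0.053 with the replicate block, and adjusted p = 0.55 with an estimated correlation). Ifit3 fell from 17.4 ± 4.08 to 1.82 ± 0.24 RPKM, Ifi44 from 9.87 ± 1.09 to 1.66 ± 0.136 and Isg15, a ubiquitin-like protein gene, from 56.4 ± 10.3 to 12.2 ± 1.12. Proliferation genes fell in 14 of 16 cases (14 adjusted over the list alone, camera adjusted p = 0.11), among them Cdc20, a mitotic regulator gene, from 10.6 ± 0.5 to 3.52 ± 0.63. Cornified keratinocyte genes fell in 16 of 19 cases (16 adjusted over the list alone, camera adjusted p = 0.14), with Krt10 at 95.4 ± 3.99 and 21.4 ± 0.983 RPKM. Asprv1, a skin protease gene, was at 123 ± 6.66 and 108 ± 12.6 (-0.20, adjusted p = 0.55). In the immature mTEC list 5 of 8 fell and 1 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.38), and the keratin gene Krt5 went from 342 ± 58.1 to 78.2 ± 9.33. In the chemokine list 5 of 10 fell and 1 rose (5 and 1; 0.86), with Xcl1 at 15.4 ± 4.24 and 0.258 ± 0.0734. The cTEC list had 7 lower and 5 higher members of 14 (7 and 5; 0.36), the list of genes linked to Fezf2 6 and 1 of 12 (6 and 1; 0.98), and the partners of Aire 12 and 2 of 19 (12 and 2; 0.97). The tuft cell list had 2 lower of 15 (1; 0.53), MHC class I processing 2 lower and 1 higher of 13 (1 and 1; 0.056) and housekeeping genes 3 lower and 1 higher of 12 (1 and 1; 0.14), in parentheses the counts adjusted over the list alone and the camera adjusted p. Centring on the housekeeping list turned the medians of the MHC class I and housekeeping lists from -0.08 and -0.09 to 0.04 for both.

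No list of markers of other cells that such a sort could hold passed camera. Called lower, beside 52.8% of all tested genes, were 10 of 15 dendritic cell and macrophage markers (2 higher; 10 and 2 adjusted over the list alone, camera adjusted p = 0.87), 8 of 10 fibroblast markers (1 higher; 8 and 1; 0.24), 6 of 10 endothelial (6; 0.94), 8 of 15 thymocyte (8; 0.99) and 4 of 8 B cell markers (1 higher; 4 and 1; 0.69), with the camera adjusted p last. Quantile normalization turned the endothelial and B cell medians from -1.25 and -0.64 to 0.12 and 0.22. Emr1, a macrophage receptor gene, was at 5 ± 0.208 and 0.198 ± 0.0684 RPKM, and the collagen gene Col1a1 at 13.2 ± 1.54 and 0.135 ± 0.0185. Of the 3 tested erythroid genes 2 were lower, with a median of -1.15 that was 0.15 after quantile normalization. For the cTEC, MHC class I, tuft cell, chemokine, testis, Aire partner, housekeeping, thymocyte, dendritic cell and B cell lists the median was negative while camera's direction was up, since camera sets the t-statistics of a list against those of all other genes, whose own balance was downward. fry, which compares no list with other genes, called 30 lists, and with an estimated correlation camera called 0. The replicate block left 10238 genes lower and 1854 higher and 14 lists passed.

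In mTEClo the genotype changed fewer genes than in mTEChi. The chitinase-like genes Chi3l3 and Chi3l4 (chromosome 3) rose in KO mTEClo from 27.8 ± 4.93 to 252 ± 23.8 and from 32.1 ± 3.31 to 293 ± 47.1 RPKM (3.18, adjusted p = 2.5e-06, and 3.18, adjusted p = 3.0e-07). Ndufa4l2, a mitochondrial protein gene, rose from 0.325 ± 0.0751 to 4.94 ± 0.579, Olfr960 from 0.199 ± 0.162 to 2.67 ± 0.827 and Ctla4 from 0.402 ± 0.0863 to 5.13 ± 2 RPKM. Igj, the immunoglobulin J chain gene, fell from 7.11 ± 2.97 to 0.171 ± 0.0599 RPKM, and Reg3b, Sbpl, Tmem212 and Ctrb1 fell from 1.19 to 2.16 RPKM in WT to under 0.1 or to 0. Igj and Reg3b lost their calls with voom, and Reg3b also without WT replicate 2 (-3.31), WT replicate 3 (-3.62), KO replicate 2 (-3.73) or KO replicate 3 (-3.53). In all, 1542 genes were called higher and 1563 lower (593 and 321 by 2-fold or more; 1548 and 1465 with the replicate block). The counts moved by over 1.5 times when centred on the housekeeping list, to 825 and 4210, which shifted the median of all genes from -0.04 to -0.19. They also moved without WT mTEClo replicate 1 (909 and 881), WT replicate 3 (748 and 732), KO replicate 1 (1015 and 967) or KO replicate 2 (967 and 952), and the lower count without KO replicate 3 (1010).

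Tuft cell genes, of a chemosensory epithelial cell type, rose in KO mTEClo in 6 of 15 cases (12 adjusted over the list alone, camera adjusted p = 1.3e-06, and adjusted p = 0.51 with an estimated correlation). The cytokine gene Il25 went from 18.6 ± 5.98 to 57.9 ± 9.05 RPKM, the taste receptor gene Tas1r3 from 5.17 ± 1.41 to 12.1 ± 0.834, and Hmx2 from 4.69 ± 2.59 to 10.8 ± 0.485. Tas1r3 lost its call without WT replicate 3 (1.05), and Hmx2 with only the mTEClo libraries (1.32) and without WT replicate 1 (1.29), WT replicate 3 (0.95) or KO replicate 1 (1.29). Muscle genes rose in 9 of 21 cases (10 adjusted over the list alone, camera adjusted p = 1.5e-06, and adjusted p = 0.47 with an estimated correlation). Tnnt3 went from 0.113 ± 0.0166 to 1.36 ± 0.574, Myh4 from 0.133 ± 0.0638 to 1.16 ± 0.65 and Acta1 from 0.759 ± 0.389 to 5.5 ± 2.92 RPKM. Interferon-stimulated genes fell in 11 of 14 cases (12 adjusted over the list alone, camera adjusted p = 2.8e-09, and adjusted p = 0.23 with an estimated correlation). Irf7 was at 248 ± 14.1 and 141 ± 7.29, Oasl2 at 224 ± 9.47 and 158 ± 5.71 and Ifi44 at 77.5 ± 3.45 and 38.3 ± 3.52 RPKM. MHC class II genes fell in 3 of 10 cases (3 adjusted over the list alone, camera adjusted p = 0.0071, and adjusted p = 0.51 with an estimated correlation). H2-DMb2 went from 124 ± 13.7 to 73.4 ± 8.06, Ciita from 29.5 ± 2.66 to 21.4 ± 2.59 and H2-Eb1 from 851 ± 63.2 to 607 ± 46.1 RPKM. H2-Eb1 lost its call after quantile normalization (-0.30) and without WT replicate 1 (-0.51), WT replicate 3 (-0.43) or KO replicate 3 (-0.42).

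MHC class I processing genes fell in KO mTEClo in 3 of 13 cases (3 adjusted over the list alone, camera adjusted p = 0.019, and adjusted p = 0.57 with an estimated correlation). The peptide transporter genes Tap1 and Tap2 went from 114 ± 6.97 to 81.2 ± 2.73 and from 114 ± 5.85 to 94.5 ± 3.14 RPKM, and the peptidase gene Erap1 from 33.7 ± 2.5 to 26.4 ± 1.88. Tap2 lost its call without WT replicate 3 (-0.22) or KO replicate 1 (-0.24), and Erap1 without WT replicates 1 (-0.31) or 3 (-0.33) or KO replicates 1 (-0.31) or 3 (-0.34). Commonly assayed antigens fell in 4 of 11 cases (5 adjusted over the list alone, camera adjusted p = 0.017, and adjusted p = 0.51 with an estimated correlation). Crp went from 29.4 ± 0.936 to 7.58 ± 2.47 and Spt1 from 2.36 ± 0.408 to 0.182 ± 0.216 RPKM. Ins2 was at 0.311 ± 0.272 in WT and listed at 0 in KO mTEClo (adjusted p = 0.0037, a call lost with a pseudocount of 1 and with only the mTEClo libraries). In the mature mTEC list 3 of 14 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.27), with Cldn4, a tight junction gene, at 47.4 ± 6.35 and 90.3 ± 3.64. Aire was at 9.9 ± 2.62 and 23.6 ± 8.64 RPKM (1.22, adjusted p = 0.066). The macrophage marker Lyz2, from a list with 4 of 15 higher (4 adjusted over the list alone, camera adjusted p = 0.077), was at 25.9 ± 2.99 in WT and 88 ± 37 in KO. 6 lists passed in all, 0 with an estimated correlation and 12 with fry, and 10 passed without KO replicate 2.

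In KO cTEC, genes of medullary and differentiated epithelium were higher than in WT cTEC. The largest rises were those of the epidermal differentiation genes Sprr4 and Crct1, of Calm4 (0.364 ± 0.209 to 11.6 ± 3.15 RPKM), of S100g, a calcium-binding protein gene (1.57 ± 0.303 to 46.7 ± 26.6), and of Skint2 (1.63 ± 0.649 to 38.9 ± 18.7). Aire was at 4.47 ± 2.69 RPKM in WT and 52.8 ± 37.3 in KO cTEC (3.49, SE 0.428, adjusted p = 4.1e-05). 2593 genes were called higher and 1315 lower, 1513 and 198 of them by 2-fold or more (2616 and 1271 with the replicate block). These calls rest on the spread pooled over all 18 libraries: with only the 6 cTEC libraries in the model, 12 genes were called higher and 6 lower. Without KO cTEC replicate 1 as well these were 6 and 0, and all 42 genes named for this comparison lost their calls. Each of 69 genes at 50 RPKM or more in KO mTEChi and 32-fold or more above WT cTEC was higher in KO cTEC, by a median of 16.5%, 6.93% and 4.53% of the difference between KO mTEChi and WT cTEC in replicates 1, 2 and 3. By the same rule KO mTEClo gave 4 genes, with medians of 22.8%, 18.3% and 14.6%. Of the 2593 genes, 72.3% were still called higher without that library in the model of the other 17. The lower count was 732 without it, 676 without WT cTEC replicate 1, 2147 without KO cTEC replicate 3, 2159 after quantile normalization (2213 higher) and 3347 when centred on the housekeeping list (1853 higher), which shifted the median of all genes from -0.01 to -0.13.

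**Figure D4:**
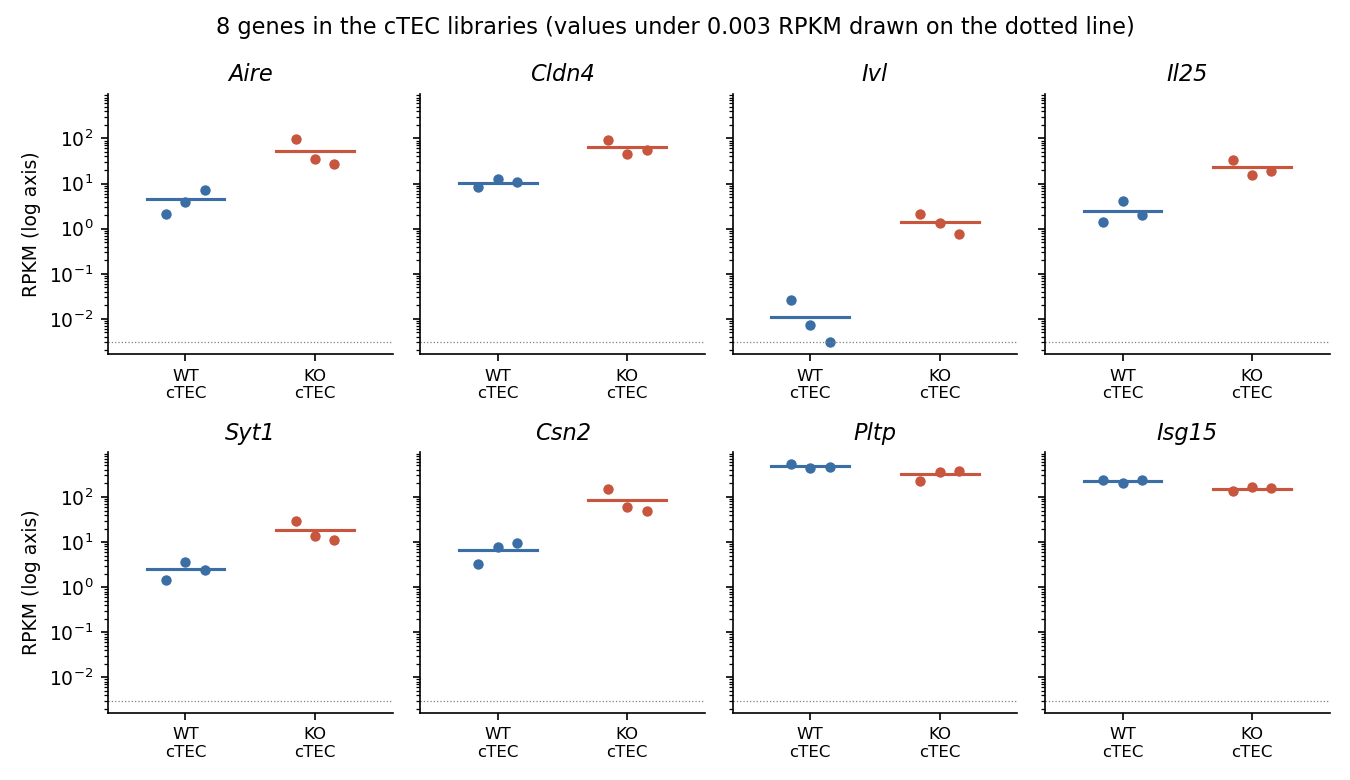
RPKM of 8 genes in the WT (blue) and KO (red) cTEC libraries on a log axis (points, 3 libraries per group, lines at the group means, values near 0 drawn on the dotted line). Aire, Cldn4, Ivl, Il25, Syt1 and Csn2 are higher in each KO library than in any WT library, and 1 KO library holds the most of each.

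Tuft cell genes were higher in KO cTEC in 15 of 15 cases (15 adjusted over the list alone, camera adjusted p = 4.6e-13, and adjusted p = 0.31 with an estimated correlation). Il25 was at 2.49 ± 1.36 and 22.8 ± 9.65, Ltc4s, a leukotriene synthase gene, at 5.88 ± 1.53 and 28.5 ± 11.8 and Hmx2 at 0.399 ± 0.124 and 2.72 ± 1.22 RPKM. Cornified keratinocyte genes were higher in 13 of 19 cases (15 adjusted over the list alone, camera adjusted p = 3.0e-11, and adjusted p = 0.29 with an estimated correlation). The involucrin gene Ivl went from 0.0112 ± 0.0134 to 1.38 ± 0.667, Sprr1a from 8.19 ± 1.17 to 59.6 ± 14.5, and Spink5 from 6.43 ± 1.5 to 23.2 ± 3.39 RPKM. Mature mTEC genes were higher in 9 of 14 cases (11 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.5e-06, and adjusted p = 0.32 with an estimated correlation). Cldn4 was at 10.5 ± 2.01 and 64.5 ± 25.8 and Cldn3 at 5.47 ± 1.27 and 31.5 ± 10.9. Genes linked to Fezf2 were higher in 6 of 12 cases (6 adjusted over the list alone, camera adjusted p = 0.0022, and adjusted p = 0.29 with an estimated correlation). Fezf2, a transcription factor gene, was at 5.7 ± 1.34 and 21.5 ± 9.43 RPKM. The NF-kB list had 5 of 13 higher (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0033, and adjusted p = 0.60 with an estimated correlation). Nfkbia was at 145 ± 22.6 and 286 ± 77.1 and Tnfaip3 at 36.9 ± 5.62 and 84.6 ± 30.2.

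Brain genes were higher in KO cTEC in 7 of 19 cases (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0063, and adjusted p = 0.29 with an estimated correlation). The synaptic genes Syt1 and Snap25 were at 2.49 ± 1.1 and 18.3 ± 10.3 and at 0.035 ± 0.0299 and 0.701 ± 0.5, and the myelin gene Mag at 0.78 ± 0.321 and 6.66 ± 2.91 RPKM. Commonly assayed antigens were higher in 6 of 11 cases and lower in 1 (6 and 1 adjusted over the list alone, camera adjusted p = 0.021, and adjusted p = 0.37 with an estimated correlation). Csn2 was at 6.8 ± 3.2 and 85.4 ± 54, Resp18 at 3.37 ± 2.59 and 26.5 ± 21.5 and Gad1 at 0.0455 ± 0.0544 and 0.734 ± 0.56. Stomach and intestine genes were higher in 7 of 24 cases (7 adjusted over the list alone, camera adjusted p = 0.021, and adjusted p = 0.37 with an estimated correlation). Vil1 was at 0.922 ± 0.315 and 6.23 ± 3.62. Muscle genes were higher in 5 of 21 (5 adjusted over the list alone, camera adjusted p = 0.042, and adjusted p = 0.60 with an estimated correlation). Myog was at 0.196 ± 0.155 and 3.04 ± 1.76 RPKM.

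Lower in KO cTEC were interferon-stimulated genes, 8 of 14 (9 adjusted over the list alone, camera adjusted p = 2.5e-05, and adjusted p = 0.31 with an estimated correlation). Oasl2 was at 192 ± 4.34 and 150 ± 4.57 and Isg15 at 229 ± 18.4 and 153 ± 16.9 RPKM. The cTEC list passed downward with 1 of 14 called (1 adjusted over the list alone, camera adjusted p = 0.045, and adjusted p = 0.66 with an estimated correlation), the lipid transfer gene Pltp, at 482 ± 53 and 320 ± 83, a call lost without WT replicate 1 (-0.53). Thymocyte genes passed downward with 2 of 15 called (4 adjusted over the list alone, camera adjusted p = 0.0022, and adjusted p = 0.60 with an estimated correlation), among them Ptcra, at 1.37 ± 0.746 and 0.311 ± 0.217. Fibroblast genes were lower in 4 and higher in 1 of 10 cases (4 and 1 adjusted over the list alone, camera adjusted p = 0.047, and adjusted p = 0.55 with an estimated correlation). Col5a1 was at 6.75 ± 0.65 and 3.83 ± 0.642. Partners of Aire were lower in 4 and higher in 1 of 19 cases (4 and 1 adjusted over the list alone, camera adjusted p = 0.047, and adjusted p = 0.32 with an estimated correlation). The 5 largest falls were those of Tmem212 (1.53 ± 0.726 to 0.0344 ± 0.0596), Fam183b (1.46 ± 0.872 to 0.0325 ± 0.0563), Rpph1, Prrt1 and Nutf2. Leaving out single libraries ended the calls of Rpph1 (every one but KO replicate 1; -2.15 to -2.92) and Nutf2 (WT replicate 3 or KO replicate 1, both -1.53), and voom ended that of Nutf2 too (-1.71). Markers of other cells that were higher in KO cTEC were Lyz2, at 38 ± 17.7 and 119 ± 24 RPKM (dendritic cell and macrophage list, 3 of 15 higher, 3 adjusted over the list alone, camera adjusted p = 0.087), and Cd79b, at 2.79 ± 1.43 and 14.9 ± 7.58 (B cell list, 1 of 8, 1 adjusted over the list alone; 0.45; median 0.18, and -0.12 after quantile normalization).

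**Figure D5:**
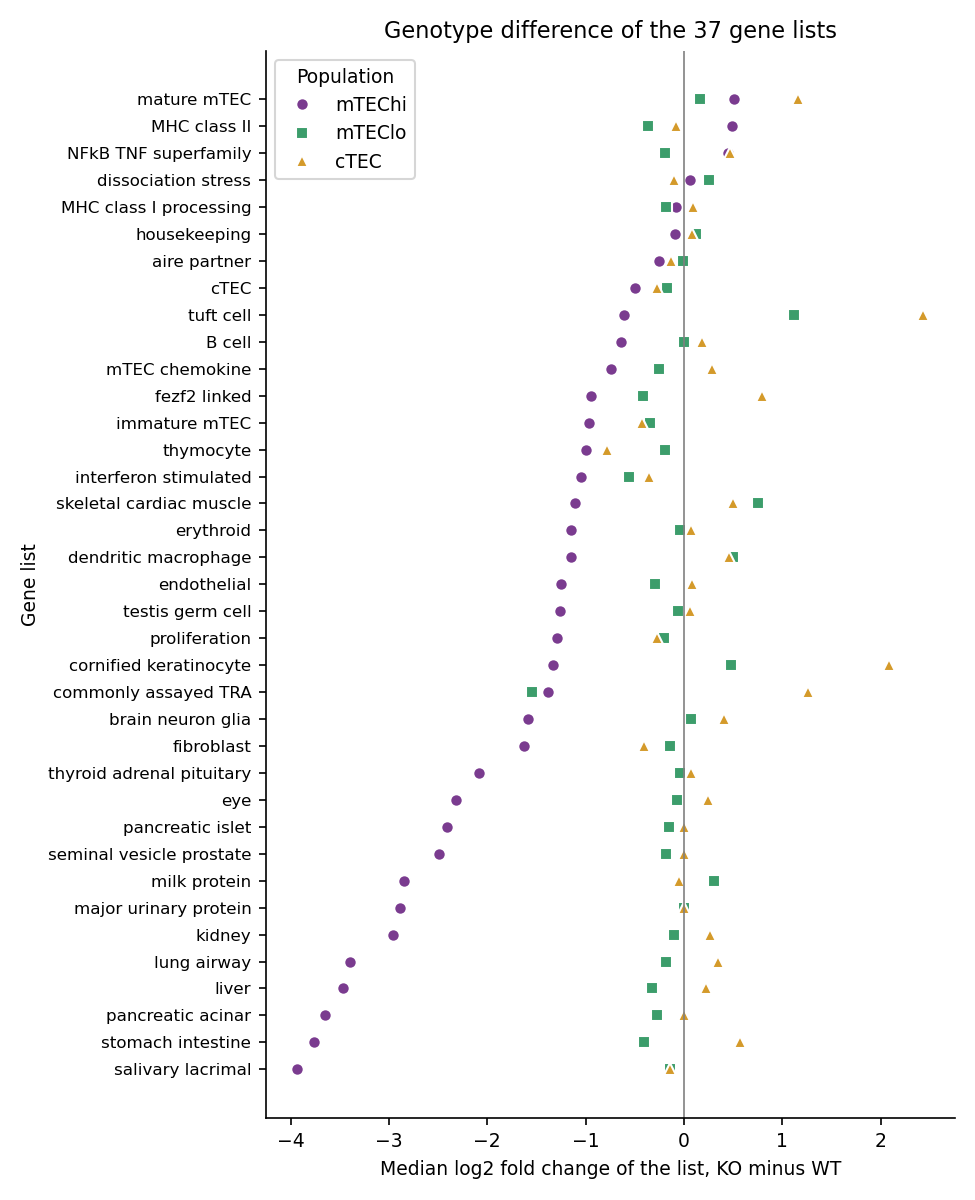
Median log2 fold change, KO minus WT, of each of the 37 gene lists in mTEChi (circles), mTEClo (squares) and cTEC (triangles), n = 3 libraries per group. Tissue lists reach -3.93 in mTEChi, where the median of all genes is -0.39, and tuft cell genes reach 1.12 in mTEClo and 2.44 in cTEC, while the testis, B cell, endothelial, erythroid and dissociation stress medians in mTEChi change sign after quantile normalization.

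The genotype effect itself differed between populations. The effect in mTEChi was lower than that in mTEClo for 7950 genes and higher for 1169, and lower than that in cTEC for 8714 and higher for 997. After quantile normalization, which moves the median of all genes, these were 3550 and 4559, and 3951 and 5343, and centred on the housekeeping list 5254 and 2454 against mTEClo. Of the lists, 18 and 19 passed camera. With an estimated correlation the salivary and major urinary protein lists still passed against mTEClo (adjusted p = 0.034 for both). In the same test 7 lists passed against cTEC: islet (adjusted p = 0.048), acinar, liver, major urinary protein, salivary, seminal vesicle, and stomach and intestine genes (adjusted p = 0.034 for each of these 6). MHC class II genes had a higher effect in mTEChi than in mTEClo in 9 of 10 cases (9 adjusted over the list alone, camera adjusted p = 6.8e-10, and adjusted p = 0.074 with an estimated correlation). The thymocyte list passed upward against cTEC (camera adjusted p = 0.027, and adjusted p = 0.67 with an estimated correlation) with no member called and a median of -0.17, which was 0.90 after quantile normalization and 0.09 when centred on the housekeeping list.

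The genes called lower in KO mTEChi were followed in the other populations, whose libraries entered that call only through the pooled spread. Same-numbered libraries of a genotype may share preparations, though, so a difference between preparations could carry over. In mTEClo 63.6% of the genes called lower in KO mTEChi had a negative log2 fold change, against 46.5% of other genes (camera p = 1.6e-05, and p = 0.010 with an estimated correlation). In cTEC the shares were 57.5% and 43.4% (camera p = 1.1e-05, and p = 0.0093 with an estimated correlation). For those lower by 2-fold or more, 61.8% were negative in mTEClo, against 52.8% of other genes (camera p = 0.010, and p = 0.027 with an estimated correlation), and 51.1% against 50.7% in cTEC (camera p = 0.12).

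A further comparison sets 2 classes of genes side by side, called dependent and independent by the genotype difference in mTEChi. The dependent class, 29.5% of tested genes, held 12 of 16 proliferation, 14 of 19 cornified keratinocyte, 7 of 14 interferon-stimulated and 0 of 12 housekeeping genes. Its falls are not shown to be direct effects of Aire. Of all 10269 genes called lower, 46.3% were still called lower after quantile normalization. The 5741 genes lower by 2-fold or more in KO mTEChi had a median of 1.45 RPKM in WT and 0.161 in KO mTEChi, and 9.91% reached 10 RPKM in WT mTEChi. Of the 5741 genes, 2447 had under 0.1 RPKM in KO mTEChi. The 803 Aire-independent mTEChi genes had a median of 5.32 RPKM in WT and 5.53 in KO mTEChi, and 37.5% reached 10 RPKM. In WT mTEClo 84.6% of the independent and 63.4% of the dependent genes were at 0.1 RPKM or more. The requirement of a narrow interval favours well-measured and so abundant genes, and both classes were defined with the KO mTEChi libraries, so the difference in level partly follows from the definitions. With a log2 fold change of at least 2 over cTEC there were 337 independent genes. Members of the fixed lists among the independent genes, picked out after the classes were known, included Cd40, Fezf2, Relb and Nfkb2 of the mTEC and NF-kB lists, and Calml3, Asprv1 and Dsg1a of the keratinocyte list. Others were Ctrl of the acinar list, and Mbp, Snap25, Actn3, Casq1, Tnnt2, Foxj1 and Lhb of other tissue lists.

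Genes of each class lay next to each other on chromosomes more often than random sets of tested genes matched on mean expression over all 18 libraries. The sets were not matched on level in WT mTEChi or on restriction to a tissue, and overlapping genes counted as neighbours. The nearest tested neighbour was of the same class for 47.0% of the dependent genes, against 31.6% in random sets (95% of sets from 30.4% to 32.9%), and for 11.8% of the independent genes, against 4.1% (2.37% to 6.1%). None of 1000 random sets reached the observed share in either class. When only neighbours with another symbol stem counted, the shares were 35.3% against 25.6% and 10.1% against 3.67%.

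The WT populations were then compared to describe the steady state. mTEChi expressed Aire at 677 ± 17.9 RPKM against 9.9 ± 2.62 in mTEClo, and Hdc, the histidine decarboxylase gene, at 286 ± 14.1 against 6.49 ± 1.01. The largest rises were in Cytl1, Klk4, Nts, Gstm3 and Pgc (54.8 ± 5.35 against 0.455 ± 0.133 RPKM), and the largest falls in Gas1 (4.44 ± 1.12 against 150 ± 20.4), Mgp, Fst, Boc and Vwa1. Of all genes 8097 were higher and 6055 lower in mTEChi (6060 and 1886 by 2-fold or more), and upper-quartile scaling, which moves the median of all genes from 0.12 to 0.41, gave 10283 higher and 3531 lower. After quantile normalization the balance turned round, with 5761 higher, 7651 lower and a median of -0.13. All 15 tissue lists passed upward, with medians from 1.59 to 4.51. With an estimated correlation 9 lists passed: islet, acinar, liver, major urinary protein, salivary, seminal vesicle, and stomach and intestine genes (adjusted p = 0.048 for each) and eye and Fezf2-linked genes (0.049 for both). Proliferation genes were higher in 14 of 16 cases (14 adjusted over the list alone, camera adjusted p = 0.0013, and adjusted p = 0.34 with an estimated correlation). Cdk1 was at 10.5 ± 2.1 and 1.64 ± 0.131 RPKM. Lower in mTEChi were immature mTEC genes in 7 of 8 cases (7 adjusted over the list alone, camera adjusted p = 0.00016, and adjusted p = 0.075 with an estimated correlation). Krt14 was at 132 ± 15.3 and 853 ± 83.3. Interferon-stimulated genes were lower in 11 of 14 (11 adjusted over the list alone, camera adjusted p = 9.9e-06, and adjusted p = 0.075 with an estimated correlation). Irf7 was at 44.2 ± 5.65 and 248 ± 14.1. Tuft cell genes were lower in 12 of 15 cases (12 adjusted over the list alone, camera adjusted p = 0.0012, and adjusted p = 0.42 with an estimated correlation). Immediate early genes of the dissociation stress list were lower in 12 of 12 (12 adjusted over the list alone, camera adjusted p = 0.0004, and adjusted p = 0.26 with an estimated correlation). Fos was at 366 ± 38.4 and 1337 ± 219. Dendritic cell and macrophage markers were higher in mTEChi in 13 of 15 cases and B cell markers in 7 of 8 (13 and 7 adjusted over the list alone, camera adjusted p = 0.0023 and 0.007, and adjusted p = 0.26 and 0.20 with an estimated correlation).

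Against cTEC, WT mTEChi was higher for 9063 and lower for 6178 genes (6942 and 2298 by 2-fold or more; 11174 and 3853 after upper-quartile scaling, which moves the median of all genes from 0.25 to 0.57). After quantile normalization 6344 were higher and 8319 lower, with a median of -0.15. Pgc, Ctrb1, Tff3, Pyy and Fabp6 rose most, and Scn1a, Fmod, Gas1, Thbd and Prelp fell most. Fezf2 was at 219 ± 8.22 RPKM in mTEChi and 5.7 ± 1.34 in cTEC. The cTEC list was lower in 10 of 14 cases and higher in 3 (10 and 3 adjusted over the list alone, camera adjusted p = 0.0016, and adjusted p = 0.29 with an estimated correlation). Cxcl12 was at 2.62 ± 0.194 against 121 ± 18.1 and the cathepsin gene Ctsl at 98 ± 20.1 against 1052 ± 161 RPKM. 27 lists passed, and islet, acinar, liver, salivary, and stomach and intestine genes also with an estimated correlation (adjusted p = 0.033 for each).

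Between WT mTEClo and cTEC, 4779 genes were higher and 3533 lower in mTEClo (2462 and 1095 by 2-fold or more; 3923 and 4714 after quantile normalization, which moves the median of all genes from 0.04 to -0.06). Cornified keratinocyte genes were higher in 18 of 19 cases (18 adjusted over the list alone, camera adjusted p = 7.6e-12, and adjusted p = 0.26 with an estimated correlation). Crct1 was at 12.4 ± 3.04 against 0.0367 ± 0.0206 RPKM. Tuft cell genes were higher in 15 of 15 (15 adjusted over the list alone, camera adjusted p = 1.9e-08, and adjusted p = 0.41 with an estimated correlation). The cTEC list was lower in 12 of 14 (12 lower and 1 higher adjusted over the list alone, camera adjusted p = 1.7e-09, and adjusted p = 0.26 with an estimated correlation). Kitl was at 3.2 ± 0.343 against 34.5 ± 4.18 RPKM. The islet amyloid gene Iapp was at 29.1 ± 6.82 in mTEClo and 0.375 ± 0.337 in cTEC. Endothelial markers were higher in 9 of 10 cases and thymocyte markers lower in 11 of 15 (9 and 13 adjusted over the list alone, camera adjusted p = 0.00042 and 0.00048, and adjusted p = 0.37 and 0.73 with an estimated correlation). Of the 9 lists passed, 0 passed with an estimated correlation.

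Within the KO the populations still differed. KO mTEChi was higher than KO mTEClo for 4548 and lower for 8500 genes (2797 and 3968 by 2-fold or more), and higher than KO cTEC for 5174 and lower for 8007 (3219 and 3835). Upper-quartile scaling turned both balances round, to 6436 higher and 5851 lower and to 7518 and 5132, with medians of all genes moving from -0.22 to 0.03 and from -0.14 to 0.13. Centring on the housekeeping list did so against cTEC, with 6918 and 5733. The cytokine genes Il13, at 366 ± 13.5 against 4.45 ± 2.26 RPKM in mTEClo, and Il4, at 19.2 ± 2.02 against 0.236 ± 0.14, were among the 5 largest rises with Olfr1136, Lrat and Marc1. Mfap4, Gas1, Lox, Cxcl14 and Col6a2 fell most. Against cTEC, Fgf21 (314 ± 32.8 against 9.84 ± 9.23), Cyp26a1, Siglec15, Apol11a and Crhbp rose most, and Gas1, Pmp22, Scn1a, Il33 and Fmod fell most. MHC class II genes were higher than in KO mTEClo in 10 of 10 cases (10 adjusted over the list alone, camera adjusted p = 2.2e-07, and adjusted p = 0.22 with an estimated correlation), and genes linked to Fezf2 in 10 of 12 (10 adjusted over the list alone, camera adjusted p = 0.00013, and adjusted p = 0.18 with an estimated correlation). Of the tissue lists, liver, testis, stomach and intestine, and thyroid, adrenal and pituitary genes still passed upward against mTEClo, with medians of 0.50, 0.93, 0.88 and 0.67 (camera adjusted p = 0.006, 0.0046, 0.015 and 0.0046, and adjusted p = 0.30, 0.22, 0.30 and 0.30 with an estimated correlation). 16 lists passed against mTEClo and 17 against cTEC, none with an estimated correlation, when the smallest adjusted p was 0.18 and 0.25.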

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

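The tests of dendritic cell and macrophage markers and of housekeeping genes for the interferon-stimulated genes, the test of depth for the number of detected genes, and that of genes by classes of level were chosen only after the result was seen. The results below stand here because the genotype effect differed between populations by a test of the difference itself.

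In KO mTEChi 10269 of 19451 genes fell and 1862 rose (4808 and 6064 after quantile normalization, which makes the distributions alike and turns the balance round), and 3034 fewer genes were detected than in WT mTEChi. The fall was not equal for all genes, since the housekeeping list had a median of -0.09 and all genes one of -0.39. Making distributions of such unlike breadth alike may itself turn genes upward, so the 6064 rises may partly follow from that step. A sort with fewer mature mTEC would lower the mature mTEC markers, but those other than Aire had a median log2 fold change of 0.50. This does not settle the question, since the hi gate, whose protein is not stated, may itself select for such markers. Other cells diluting the mTEC were expected to raise a median of the 5 other cell lists by 1 or more. The highest was -0.64, and 0.22 after quantile normalization, which turned the B cell and endothelial medians positive. This does not settle dilution, since a fall of these genes in mTEC themselves could hide a rise. In WT mTEChi against mTEClo the B cell, dendritic cell and thymocyte medians were already 3.35, 2.30 and 0.75, and the fibroblast and endothelial ones -0.77 and -0.70. Shallower libraries would lower counts of detected genes, yet libraries of 1 group with as large a difference in depth differed by at most 202 genes. KO mTEChi replicate 2, at 11.6 Gb, detected 16512 genes, and WT mTEChi replicate 1, at 10.8 Gb, 19558. If depth caused the fall, genes of the same level that are not higher in mTEChi than in cTEC should also fall. They did, with a median of -0.53. The median of all genes, -0.394, did not follow depth, however. It was -0.388 without KO replicate 1, the shallowest at 6.25 Gb, and -0.404 without WT replicate 3, the deepest at 15.6 Gb. Leaving out other mTEChi libraries gave -0.379 to -0.420. These values argue against depth as the source of the fall over all genes, while genes of the same level were not tested this way. Genes 2-fold or more higher in mTEChi than in cTEC fell more than others in each of 10 classes of level, with a smallest gap between the medians of -0.82 when 1 WT mTEChi library set the class and level and the change was taken against the other 2. The ranges between the quartiles of the 2 sets overlapped, so this test alone does not settle the part of depth in that gap. A loss of Aire's own effect on transcription may contribute to the fall, but the deletion in these mice was not tested apart from the genotype label.

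In KO cTEC, genes of mTEC, tuft cells and keratinocytes were higher than in WT cTEC, though none of these lists passed with an estimated correlation (adjusted p = 0.32, 0.31 and 0.29). A candidate explanation is mTEC carried into the KO cTEC sort: 100% of 69 genes at 50 RPKM or more in KO mTEChi and 32-fold or more above WT cTEC were higher in KO cTEC, by a median of 16.5%, 6.93% and 4.53% of the difference between KO mTEChi and WT cTEC in replicates 1, 2 and 3. The 4 genes that KO mTEClo gave by the same rule had medians of 22.8%, 18.3% and 14.6%, which differ less between replicates. The sort was meant to exclude such cells. Replicate 1 alone does not account for all of it, since 72.3% of the genes were still called higher without it, but with only the 6 cTEC libraries 12 genes were called higher, so its part stays open. A change in KO cTEC themselves also stays open and was not tested.

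Interferon-stimulated genes were lower in the KO in all 3 populations, but with an estimated correlation the list passed in none (adjusted p = 0.55, 0.23 and 0.31 in mTEChi, mTEClo and cTEC), and with the replicate block not in mTEChi (0.053). Fewer dendritic cells and macrophages in the KO sort of mTEClo would lower their marker list. It had a median of 0.50 there, and 0.345 as the lowest under any scaling tried, although it did not pass camera (adjusted p = 0.077). This does not decide, since mTEChi carried into that sort could raise the list. Its medians in mTEChi against mTEClo were 2.30 in WT and 1.16 in KO. In cTEC the median was 0.46, and 0.196 after quantile normalization (camera adjusted p = 0.087), which does not decide, since mTEC carried into that sort could raise it. The list was higher in mTEChi than in cTEC, with medians of 1.59 in WT and 0.22 in KO. Lyz2, which rose in KO cTEC, was among the Aire-independent mTEChi genes. In mTEChi a smaller number of such cells stays open: the same markers had a median of -1.15, with 10 of 15 lower and 2 higher. After quantile normalization their median was -0.19, and that of the interferon-stimulated list -0.92. The tables argue against a lower scale of the KO libraries of mTEClo and cTEC. The housekeeping list had medians of 0.12 and 0.085 there, and -0.04 for both after centring on that list, by its construction. A difference in the health or housing of the mice, or an effect of the genotype on interferon signalling, could give such a fall, and stays open because the labels name no batch, litter or room.

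Values of the remaining results are genotype effects (KO minus WT, log2) in mTEChi minus those in another population, and values of genes listed at 0 in a group depend on the added 0.1. Against mTEClo the effect in mTEChi was higher for Fam19a1 1.69, Olfr1138 2.53, Rgr 1.25, Nfam1 1.47, Ppp1r3c 0.90, Defb33 2.34, Ptchd4 2.27, Crp 1.13, Ciita 0.91, H2-DMb1 0.94, H2-Oa 1.03, H2-Ob 1.30, Traf6 0.60, Igj 3.35, H2-DMb2 1.05 and H2-Eb1 0.97. It was lower for Sst -6.67, Crabp1 -6.13, Nts -5.91, Cytl1 -7.17, Tac2 -6.07, Sbpl -4.35, Ppy -4.70, Spt1 -4.45, Gstm3 -6.57, Pgc -5.37, Tff3 -3.10, S100a8 -2.71, Ins2 -5.19, Obp1a -3.64 and Reg2 -6.05. Also lower were Fga -4.88, Alb -4.92, Mup4 -4.32, Smr3a -4.81, Svs4 -5.34, Cryba1 -4.79, Gkn2 -6.18, Sftpb -4.23, Kap -4.58, Ifi44 -1.48, Ifit3 -2.39, Isg15 -1.37, Ltbr -0.45, Krt10 -1.29 and Krt5 -1.69. The last of these were Cdc20 -1.04, Emr1 -4.79, Col1a1 -5.81, Xcl1 -5.32, Ndufa4l2 -3.46, Olfr960 -2.94, Chi3l3 -4.42, Chi3l4 -3.90, Ctrb1 -3.82, Il25 -1.41, Tas1r3 -1.29, Hmx2 -1.52, Tnnt3 -4.36, Acta1 -5.67, Oasl2 -0.30, Irf7 -0.85 and Lyz2 -1.57. The median of all genes against mTEClo was -0.39, so Oasl2 was not lower relative to other genes. Against cTEC that median was -0.44, so Col5a1, given below, was hardly lower. Rises in KO cTEC, which mTEC carried into that sort could give, enter the differences against cTEC. Aire, Csn2, Resp18 and Gad1, for example, were called higher in KO cTEC and not called in mTEChi. With only the cTEC libraries in the model few genes were called in cTEC. Against cTEC the effect was lower for Aire -2.82, Sprr4 -7.64, Calm4 -5.46, S100g -3.27, Crct1 -6.43, Skint2 -3.32, Cldn4 -2.06, Cldn3 -1.88, Sprr1a -3.95, Ivl -4.91, Spink5 -3.01, Ltc4s -2.59, Syt1 -2.25 and Mag -3.37. In the same test Snap25 -2.50, Myog -3.18, Tnnt2 -2.06, Vil1 -3.31, Sis -2.55, Atp4b -2.73, Fezf2 -1.86, Csn2 -2.75, Gad1 -2.87, Resp18 -3.14, Tnfaip3 -1.78, Col5a1 -0.48, Pltp -0.71 and Cd79b -2.08 were lower, and Prrt1 2.10 was higher.

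Lists that passed camera in these comparisons had these medians of the difference against mTEClo: mature mTEC 0.090, MHC class II 0.95, MHC class I processing 0.15, cornified keratinocyte -1.77, islet -1.51, acinar -3.33, liver -3.10, major urinary protein -2.97, milk protein -3.05, salivary and lacrimal -3.93, seminal vesicle and prostate -2.05, brain -1.69, eye -2.41, muscle -1.66, stomach and intestine -2.37, lung -3.38, kidney -2.81 and NF-kB 0.50. Against cTEC they were MHC class II 0.51, cornified keratinocyte -3.01, tuft cell -3.18, islet -2.85, acinar -4.00, liver -3.51, major urinary protein -2.16, milk protein -2.50, salivary and lacrimal -3.90, seminal vesicle and prostate -2.60, brain -2.25, eye -2.83, stomach and intestine -4.17, lung -3.72, kidney -3.09, thyroid, adrenal and pituitary -2.07, commonly assayed antigen -3.14, dissociation stress 0.069 (-0.024 after quantile normalization) and thymocyte -0.17 (0.90 after quantile normalization and 0.085 when centred on the housekeeping list). With an estimated correlation only 2 of these lists passed against mTEClo, major urinary protein and salivary and lacrimal, and 7 against cTEC: islet, acinar, liver, major urinary protein, salivary and lacrimal, seminal vesicle and prostate, and stomach and intestine. The thymocyte list passed upward with a negative median, since it is compared with all other genes. Differences against cTEC can come from either population. Tuft cell genes had medians of KO minus WT of 2.44 in cTEC and -0.60 in mTEChi, and acinar genes 0 and -3.65.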

How the results depend on the processing

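Centring on the housekeeping list, voom, fits without KO cTEC replicate 1 outside its own comparison, the settings for genes changed alike, and leaving out replicates for detected genes, classes, clustering and list tests were chosen after seeing the data. The planned test of read counts was not run, since whole reads cannot be recovered. Where no reason is given, the cause was not tested.

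Of 245 results for named genes, 4508 checks under the alternatives gave 4353 with the same direction and side of the threshold, 140 calls lost, 14 gained and 1 reversed direction, Ttr in mTEChi (0.068 after quantile normalization). Most losses were those of the cTEC genes: with only the compared groups 12 genes were called higher and 6 lower in KO cTEC, and without KO cTEC replicate 1 as well 6 and 0, a model with fewer libraries. The genes changed alike in all 3 populations, 272 higher and 377 lower, were 0 and 2 with only the compared groups, and 150 and 1158 when centred on the housekeeping list. They were 386 and 270 after quantile normalization, and 357 and 264 without KO cTEC replicate 1.

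A 2-fold threshold, which must lower counts, left 411 higher and 5741 lower for KO minus WT in mTEChi, 593 and 321 in mTEClo and 1513 and 198 in cTEC. It left 1886 lower for WT mTEChi against mTEClo, 2298 lower against cTEC, 2462 and 1095 for WT mTEClo against cTEC, 2797 and 3968 for KO mTEChi against mTEClo and 3219 and 3835 against cTEC, and 269 and 173 higher for the differences between genotype effects. Quantile normalization gave 6064 higher and 4808 lower in mTEChi, 2159 lower in cTEC, and 4559 and 3550, and 5343 and 3951, for the differences between genotype effects against mTEClo and cTEC, since it makes the distributions alike and so moves the median of all genes. Upper-quartile scaling left 3531 and 3853 genes lower in WT mTEChi than in mTEClo and cTEC, and 5132 lower in KO mTEChi than in cTEC. Centring on the housekeeping list gave 825 higher and 4210 lower in mTEClo, 3347 lower in cTEC, 2454 and 5254 against mTEClo and 2098 higher against cTEC.

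The share of calls that are higher moved by over 10 points with scaling in each of the 10 comparisons. In KO mTEChi it went from 15.3% to 55.8% after quantile normalization, in mTEClo from 49.7% to 16.4% when centred on the housekeeping list, and in cTEC from 66.4% to 35.6%. It fell below 50% after quantile normalization for the 3 WT comparisons (57.2% to 43.0%, 59.5% to 43.3% and 57.5% to 45.4%), and rose above 50% after upper-quartile scaling for KO mTEChi against mTEClo and cTEC (34.9% to 52.4% and 39.3% to 59.4%). The same-numbered libraries of a genotype may share a preparation, and the replicate block within genotype gave 8158 and 6071 genes higher and lower for WT mTEChi against mTEClo, 9130 and 6156 against cTEC, and 4826 and 3585 for WT mTEClo against cTEC. For KO mTEChi it gave 4581 and 8539 against mTEClo and 5164 and 8030 against cTEC, and none of its 111 checks of named genes changed a call.

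With 1 replicate left out, the counts for KO minus WT ran from 748 to 2110 higher and 732 to 2284 lower in mTEClo, and from 676 to 2147 lower in cTEC. Those that moved by over 1.5 times in mTEClo were without WT replicate 1 (909 and 881), WT replicate 3 (748 and 732), KO replicate 1 (1015 and 967), KO replicate 2 (967 and 952) and KO replicate 3 (1010 lower). In cTEC they were without WT replicate 1 (676), KO replicate 1 (732) and KO replicate 3 (2147).

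With an estimated correlation, 0 lists passed for KO minus WT in mTEChi, mTEClo and cTEC, 9 and 5 for WT mTEChi against mTEClo and cTEC, 0 for WT mTEClo against cTEC, 0 for both KO comparisons, and 2 and 7 for the differences between genotype effects. With fry the numbers were 30 in mTEChi, 12 in mTEClo, 23 for WT mTEClo against cTEC, 25 and 29 for the KO comparisons, and 30 for both differences. Without KO mTEClo replicate 2, 10 lists passed in mTEClo. With the replicate block the interferon list lost its call in mTEChi (adjusted p = 0.053) and the dissociation stress list gained one in mTEClo (0.017).

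The detected genes per library, KO minus WT in mTEClo, reversed at 1 RPKM (106.3) and without WT replicate 2 (8.5) or KO replicates 2 (17.7) or 3 (16.7), in a range from -83.3 to 17.7, for cTEC when genes above 0 were counted (-490.3), and for KO mTEChi against mTEClo and cTEC at 1 RPKM (-249.7 and -201.7). Of the genes lower in KO mTEChi by 2-fold or more, 51.1% were negative in cTEC, and camera no longer passed. The Aire-independent mTEChi genes were 337 with a log2 fold change of at least 2 over cTEC, 598 with a pseudocount of 1, and 675 to 920 with 1 replicate left out. Depth may limit genes near 0.1 RPKM most, but its effect was not tested by level. The WT mTEClo libraries, at 4.54 to 18.1 Gb, differed by 125 detected genes.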

Other observations

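The test of motile cilia genes used a list drawn up only after such genes were seen among those changed alike, with its prediction written before the list's own values. Some genes changed in the same direction in KO in mTEChi, mTEClo and cTEC: 272 were called higher and 377 lower in all 3, against 19.7 and 55.8 if the calls were independent, although the groups share 1 estimate of the spread. With only the compared groups in each model these counts were 0 and 2, since few genes are then called in cTEC, and centred on the housekeeping list 150 and 1158. The balance turned round after quantile normalization (386 and 270) and without KO cTEC replicate 1 (357 and 264). Ctla4 was higher in KO in each population (3.83, 3.33 and 3.35), and Tmem212 lower in each (-3.63, -3.65 and -3.60). Spata18 fell by 3.64, 1.98 and 1.92 on the log2 scale. Genes higher in KO mTEChi, such as Ctla4, could also rise in KO cTEC through mTEC carried into that sort. The counts do not separate this from a change in cTEC themselves.

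In a list of 30 motile cilia genes, 25 were lower and 1 higher in KO mTEChi (median -1.68, camera p = 0.0066, and p = 0.22 with an estimated correlation), and 9 lower in KO mTEClo (median -0.45, camera p = 0.0009, and p = 0.14 with an estimated correlation). In KO cTEC 4 were lower and 2 higher (median -0.14, camera p = 0.09, and p = 0.44 with an estimated correlation). A loss of cilia gene expression may thus be part of the change in mTEC, while the median of -0.14 leaves cTEC undecided. Quantile normalization moved the medians in mTEChi and cTEC to -0.50 and -0.39, and centring on the housekeeping list those in mTEClo and cTEC to -0.61 and -0.26.

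DNA of the strain in which the mutation was made, lying around Aire, could change neighbouring genes alike in all populations. Of 282 tested genes within 10 Mb of Aire, 13 changed alike, against 636 of 19168 others (odds ratio 1.41, 95% interval 0.74 to 2.47, Fisher p = 0.24). The interval leaves this open, and variants were not analysed here.

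Unequal shares of male and female mice could change genes in cTEC and mTEClo, but the largest Y-linked median was -0.19, too small for the larger changes there. Xist and Y-linked genes were found in every library. Xist had log2 fold changes of -0.36, 0.10 and 0.81 in mTEChi, mTEClo and cTEC (adjusted p = 0.46, 0.92 and 0.17).

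Chromosomal clustering of the dependent genes was predicted before it was computed, and 47.0% had a nearest neighbour of the same class, more than in any of 1000 random sets. Domains of shared regulation, or gene families in tandem, may both contribute, and neighbours with another symbol stem still gave 35.3% against 25.6%.

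For comparisons of 3 against 3 libraries only 10 splits exist, too few for a share under 0.05, and 1 of 10, the real one, gave as many calls in each. The real values and the highest other were 12131 and 1 for KO minus WT in mTEChi, 3105 and 0 in mTEClo, and 3908 and 164 in cTEC. For WT mTEChi they were 14152 and 0 against mTEClo and 15241 and 1 against cTEC, and for WT mTEClo against cTEC 8312 and 2. For KO mTEChi they were 13048 and 0 against mTEClo and 13181 and 2 against cTEC. For the differences between genotype effects 4 of 100 splits were as large in each case, with real values of 9119 and 9711 and highest others of 11082 and 11563. These counts do not decide on chance for the difference itself. Every split drawn that kept mTEChi apart by genotype gave at least 7981 calls, however the other population was mixed, and every other split at most 562, so they follow the genotype effect in mTEChi.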
